A study of Mus musculus with 14 samples.

How the data were processed

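RNA of the mouse C2C12 line, a line of skeletal muscle myoblasts, was measured by RNA sequencing in 14 libraries. Per the labels, cells grew in medium with 20% fetal calf serum (FCS) and were sampled at day 0, or were moved to a differentiation medium, renewed every other day, and sampled at day 2 or day 7. Medium DM1 held 2% horse serum (HS). Medium DM2 held 10% FCS and a cocktail used to induce fat cells, with 1 µg/ml insulin, 0.5 mM of the phosphodiesterase inhibitor IBMX, 0.5 µM of the glucocorticoid dexamethasone and 2 µM of the PPAR-gamma agonist rosiglitazone. Medium DM3 joined the 2% HS of DM1 with the cocktail of DM2. Each of the 7 groups (day 0, and DM1, DM2 and DM3 at day 2 and day 7) held 2 libraries. The labels number the replicates but do not say that they are separate cultures, so the p-values measure the spread between these libraries, which may be technical.

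Per the labels' protocols and the series' design text, poly(A) RNA went into strand-specific libraries with 11 cycles of PCR, and single-end reads of 50 bp were sequenced to a stated depth of 25 to 40 M raw reads per library. Of these reads 95 to 99% aligned, 74 to 83% in a single place, with ribosomal RNA under 5.5%. Per the submitters' processing notes and the design text, reads were aligned with STAR 2.5.1b to the mouse genome GRCm38.p5 with the Gencode vM12 annotation and counted per gene with RSEM 1.2.31. The authors deposited RSEM's expected counts, which are estimated counts that need not be whole, because RSEM divides a read that fits several genes among them. The values are not normalized: their sums differ between libraries, from 21907617 to 29784885. The table held 49671 genes, of which 20610 were at 0 in all 14 libraries, and 0 of its columns of values could not be matched to a library. Symbols came from the table, and coordinates from the Gencode vM21 annotation of GRCm38, which held 49412 of the gene identifiers. Genes were tested by identifier. Where several identifiers shared a symbol (101 symbols), the gene lists, the panel and the follow-up tests took the identifier with the highest total count.

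The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes with too few counts were removed with filterByExpr by group, which left 15973 genes. Libraries were scaled by TMM, all 14 were fitted in a single model of the 7 groups with 7 residual degrees of freedom, and each comparison was tested with the robust quasi-likelihood F test. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes in the results are from this test. Levels are CPM, counts scaled to 1e6 per TMM-scaled library, as mean ± SD over the 2 libraries of a group. Log2 fold changes carry a standard error (SE) worked out from the test. It is the absolute log2 fold change divided by the square root of its F statistic, not an error given by the fit. Comparisons were each medium and day against day 0, day 7 against day 2 in each medium, and the media against each other at each day, 15 in all, plus tests of whether the difference between DM3 and DM1, and between DM3 and DM2, itself differed between the days. DM3 against DM1 changes the cocktail at the same serum, DM3 against DM2 changes the kind and the amount of serum together at the same cocktail, and DM2 against DM1 changes both.

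A fold change against a group at 0 in both libraries is given as a lower bound, against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Floors lay between 0.101 and 0.137 CPM per library. Reads were amplified and carry no molecular identifiers, so floors and intervals cover counting error only. Leaving out 1 library moves most of these ratios by over 1.5 times as well. Other folds that moved so far, in the fit or in the counts where the library left held 3 counts or fewer, are given with their value without that library. Numbers of genes higher and lower are given under another setting where it moved the percent higher by over 5 points or a number by over 1.5 times. Day-dependent differences with such a group carry the exact conditional interval of the ratio of ratios, or a bound with the group at 0 set to the floor.

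Gene lists were written from general knowledge of muscle, fat and the cocktail's components: 28 lists with 536 symbols, all found in the table. They cover myogenic regulators and fusion, core sarcomere, fast (type II) and slow (type I) fibre, developmental sarcomere isoforms, excitation-contraction and neuromuscular junction, quiescent or reserve myoblast, atrophy and autophagy, cell cycle, contractile smooth muscle and SRF, extracellular matrix, adipocyte markers, brown or beige adipocyte, fatty acid synthesis, cholesterol synthesis, PPAR and fatty acid oxidation, insulin and IGF signalling, glucocorticoid targets, cAMP targets, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, unfolded protein and amino acid stress, interferon response, inflammatory cytokines and NF-kB, and markers of endothelial cells, of osteoblasts and chondrocytes, and of leukocytes. The leukocyte list had 1 of 13 members past the low-count filter and was not tested as a list. The other 27 were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists and 15 comparisons (405 tests). Camera asks whether a list's genes shifted in a single direction relative to other genes. A list whose genes moved both ways need not pass. Where a call was lost with the correlation estimated from the data, that adjusted p is given beside it; calls without such a value held. Counts of members are over all genes tested and, beside them, adjusted over the list alone.

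Genes named in the results were taken by a rule. They are a panel of 32 genes of muscle, fat, the cocktail and the cell cycle, then the genes with the largest fitted rises and falls in each comparison, and up to 4 members of each list described, those with the largest change among the members that passed. The second part took genes called changed, with a mean of at least 10 CPM in the higher group, no overlap between the groups, and no predicted-gene name, at 6 rises and 6 falls for the day 7 comparisons against day 0 and between media, 4 and 4 for the other pairwise comparisons, and 3 and 3 for the day-dependent differences. Values of some list members are not reported here. Outside the rule, and after their values were seen, the levels of Gapdh, Hspa5 and Atcay and the share of Gm42418 were added, and the list members Lum and Gbp2 were passed over for their low counts. Groups, tests, lists, the naming rule and the first set of alternative settings were all chosen before the data were examined.

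The alternative settings of that first set were DESeq2's size factors, library totals without further scaling, no low-count filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0 with its Wald test, a fit of the compared groups alone, counts without rounding, the replicate number as a block, and leaving out each library in turn. For lists they were the estimated correlation, fgsea 1.28.0, the block and leaving out each library. Another 3 were added after seeing the data: leaving out the 3 libraries with a low share of counts on pseudogenes, that share as a covariate, and protein-coding genes only. Myosin heavy chain isoforms are given as percent of the summed expected counts of Myh1, Myh2, Myh3, Myh4, Myh7 and Myh8, also after division by exon length.

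The pipeline was tested on simulated counts, drawn for all 14 libraries from the mean levels of the DM1 group of day 7 with the fitted dispersions, with changes added to the libraries of DM3 at day 7. Of 15208 genes tested in the simulation, 67 were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. It recovered 11.94%, 56.72% and 86.36% of these, with 6 false calls, 5.5% of its calls. DESeq2 made 148 calls on the same counts, 33 of them false. Camera called a simulated list of genes that rose and did not call a list of unchanged genes. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. These recoveries hold for a simulation in which few genes changed, while many more were called in the data. Replicates were compared over 13827 to 14598 genes per group. Their counts differed by more than sampling noise in each of the 7 groups (chi-square per degree of freedom 13.7 to 90.5), so no library was counted as a copy of another. Figures were drawn with matplotlib 3.10.9.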

Results

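RNA sequencing followed C2C12 myoblasts from growth medium (day 0, 20% FCS) into 3 differentiation media, DM1 (2% HS), DM2 (10% FCS with insulin, IBMX, dexamethasone and rosiglitazone) and DM3 (2% HS with that cocktail), at day 2 and day 7. Each of the 7 groups held 2 libraries, 14 in all, with 21907617 to 29784885 expected counts and 17750 to 21111 genes with at least 1 count. After the low-count filter 15973 genes were tested. The first principal component took 37.6% of the variance and the next 24.3%. Each level below is a mean ± SD of n = 2 libraries in CPM (counts scaled to a common library total), log2 fold changes carry their SE, and coordinates are on GRCm38.

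Library makeup differed between and within groups. Processed pseudogenes took 4.55 and 4.83% of counts in the DM2 libraries of day 7. They took less in 1 library than in the other in 3 groups: 1.68 against 3.02% at day 0, 1.60 against 2.58% in DM1 at day 2, and 0.837 against 2.84% in DM3 at day 2. The low DM3 library, replicate 2, also had fewer non-whole values (4.18%) and the 17750 genes of the lower bound above. Mitochondrial mRNA was highest in DM3 at day 7 (5.44 and 5.01%), and Gm42418, which overlaps ribosomal RNA, reached 2.08% there. The 10 most abundant genes of a library took 12.3 and 11.8% of counts in DM3 at day 7, against 5.64% in the lowest library.

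**Figure D1:**
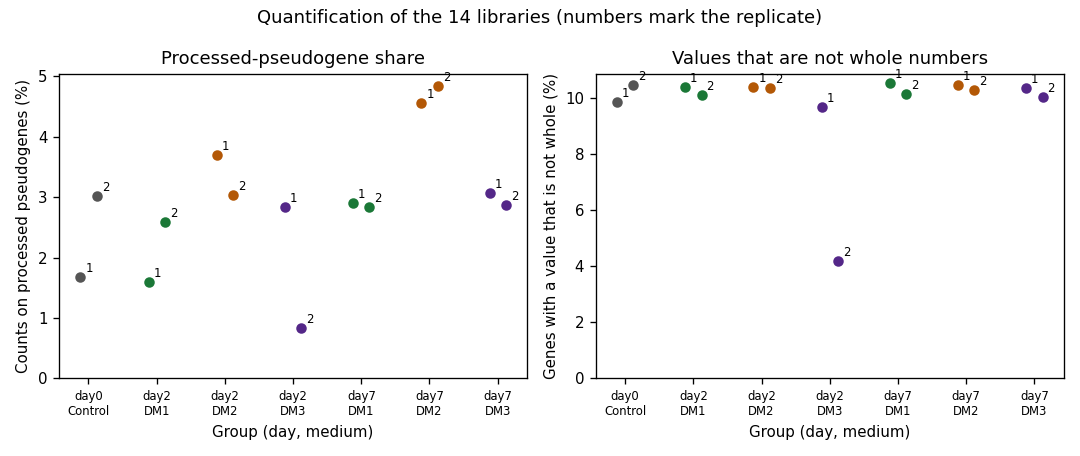
Share of counts on processed pseudogenes, and percent of genes with a value that is not whole, in each of the 14 libraries.

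In DM1, muscle genes rose and the cell cycle list fell by day 2. Embryonic myosin heavy chain Myh3 (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291) rose 105-fold over day 0, to 60.3 ± 7.38 CPM, skeletal actin Acta1 54.3-fold, calsequestrin Casq2, which stores calcium, 52.7-fold, and the thick-filament protein Mybph 52.1-fold. Myogenin (Myog), a driver of terminal differentiation, rose with log2 4.58 ± 0.17, and Myod1, its upstream regulator, fell with log2 -1.04 ± 0.16. The genes with the largest falls were the cystine transporter Slc7a11 (7.21-fold), the glutathione transferase Gsta1 (7.09-fold), whose reads can be shared with close paralogs, and the differentiation inhibitors Id3 (5.45-fold) and Id1 (4.5-fold). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 8 largest changes had adjusted p of 4.85e-09 to 8.15e-05. In all 4750 genes changed, 2422 higher and 2328 lower (2824 and 1952 under library totals alone), with 893 and 229 by at least 2-fold. The count was 2868 (1646 higher, 1222 lower) without day 0 replicate 1 and 3582 (1659 and 1923) without replicate 2. It was 2916 (1579 and 1337) and 3036 (1690 and 1346) without replicate 1 or 2 of DM1 at day 2, and 2134 (1253 and 881) without the 3 libraries of low pseudogene share. Without day 0 replicate 2, Casq2 rose 103-fold.

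Among lists, 17 of 22 rose and 0 fell (17 and 1 adjusted over the list alone) of the core sarcomere (camera adjusted p = 6.45e-17), led by creatine kinase Ckm, at 403-fold (95% counting interval 71.9 to 16000). Cell cycle genes went the other way: 26 of 30 fell and 0 rose (28 and 0 adjusted over the list alone), with camera adjusted p = 1.28e-12, and the ribonucleotide reductase subunit Rrm2 was 2.37-fold lower. Cholesterol synthesis was raised as a list, 21 of 22 rose and 0 fell (22 and 0 adjusted over the list alone), with camera adjusted p = 3.49e-16. Its members included the isomerase Idi1 (2.53-fold). For the interferon response 8 of 22 rose and 0 fell (12 and 0 adjusted over the list alone), with camera adjusted p = 4.11e-05, but adjusted p = 0.0653 with an estimated correlation. Ifit1, an antiviral RNA-binding protein, rose 10.4-fold. Ifit1 rose 5.34-fold without day 0 replicate 1 and at least 10.7-fold without replicate 2.

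By day 7 in DM1, glucocorticoid targets had risen and cell cycle genes had fallen as lists. Cilp, a cartilage matrix protein, had 0 counts at day 0 and rose at least 267-fold, to 27.9 ± 2.17 CPM. The serine protease inhibitors Serpina3n (1801-fold) and Serpina3m (3500-fold (95% counting interval 628 to 138000)) rose, although near-identical copies of this cluster can share reads. Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075), which makes active glucocorticoid from its inactive form, rose 483-fold, to 136 ± 5.72 CPM, the secreted factor Angptl7 by 1170-fold (95% counting interval 209 to 46200), and the muscle chaperone Hspb7 by 776-fold (95% counting interval 214 to 6410). Myog rose with log2 4.70 ± 0.17 and Myh3 with 7.97 ± 0.25. The largest falls were in the replication factors Cdc6 (37.8-fold) and Mcm3 (28.3-fold), the carbonic anhydrase relative Car8 (30.7-fold), the natriuretic peptide receptor Npr3 (27.1-fold), the deubiquitinase Usp43 (26.5-fold) and the cell cycle regulator Mybl2 (25.6-fold). Adjusted p of these 12 genes lay at 1.81e-11 to 2.27e-07 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Changed genes numbered 8545, 4421 higher and 4124 lower (3858 and 4479 with only these groups fitted), 2156 and 1376 by at least 2-fold. Serpina3n rose 932-fold without day 0 replicate 1 and at least 1560-fold without replicate 2.

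Of the cell cycle members 30 of 30 fell and 0 rose (30 and 0 adjusted over the list alone), with camera adjusted p = 9.35e-30. Glucocorticoid targets were raised in this medium, which per the labels held no dexamethasone: 13 of 19 rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 7.91e-08. They included the metallothioneins Mt2 (47.5-fold) and Mt1 (29.8-fold), the transcription factor Cebpd (26.4-fold) and Fkbp5, a brake on the receptor (log2 2.46 ± 0.076). Extracellular matrix genes rose, 18 of 25 rose and 2 fell (19 and 2 adjusted over the list alone), with camera adjusted p = 6.67e-08, but adjusted p = 0.162 with an estimated correlation, among them the proteoglycan Dcn (99.9-fold) and collagen Col6a2 (41.3-fold); collagen Col1a1 reached 1236 ± 177 CPM. In the atrophy and autophagy list 10 of 14 rose and 1 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00119, but adjusted p = 0.0929 with an estimated correlation, including the ubiquitin ligase Fbxo32 (6.12-fold).

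Between day 2 and day 7 in DM1, Serpina3m went from 0 counts to 60.3 ± 1.81 CPM (at least 479-fold), Serpina3n rose 1005-fold, Cilp 171-fold, and the protease inhibitor Ctla2a, which has the close paralog Ctla2b, 173-fold. Myog did not pass (log2 0.12 ± 0.14), while Myh3 rose 2.39-fold. Cdc6 fell 21.2-fold, Mcm3 18-fold, thymidine kinase Tk1 14.3-fold and Mcm5 13-fold; the 8 genes' adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 9.71e-11 to 1.6e-06. The 5482 genes changed were 2691 higher and 2791 lower, 917 and 712 by at least 2-fold. The count was 3631 (1726 higher, 1905 lower) without DM1 replicate 1 of day 2 and 3692 (1690 and 2002) without replicate 2. Cholesterol synthesis members fell here, 17 of 22 fell and 0 rose (19 and 0 adjusted over the list alone), with camera adjusted p = 5.18e-07, but adjusted p = 0.144 with an estimated correlation. Without DM1 replicate 2 of day 2, Serpina3n rose 1960-fold (95% counting interval 541 to 16200).

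In DM2, glucocorticoid targets rose by day 2. The lubricating proteoglycan Prg4 rose 208-fold, to 305 ± 57.8 CPM, and the G-protein regulator Rgs2, a cAMP target, 209.6-fold. The acute-phase protein Orm1 rose by 1120-fold (95% counting interval 201 to 44400), and Ceacam10, an adhesion gene of a cluster of close paralogs, at least 99.7-fold. Myog rose with log2 3.89 ± 0.16, and Myh3 reached only 4.7 ± 0.77 CPM. Falls were led by the protease inhibitor Serpinb2 (43-fold), the tubulin Tubb3 (31.9-fold), the exchange factor Dock8 (28-fold) and the actin-binding Xirp1 (20-fold). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave these 8 genes adjusted p of 7.9e-10 to 1.07e-06. A total of 7935 genes changed, 3754 higher and 4181 lower, 1588 and 1333 by at least 2-fold.

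Glucocorticoid targets rose in DM2 at day 2 as a list, 13 of 19 rose and 1 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 9.6e-11. Tsc22d3, a repressor of inflammation, rose 16.1-fold. Targets of cAMP went both ways, 8 of 17 rose and 7 fell (8 and 7 adjusted over the list alone), with camera adjusted p = 0.521. The phosphodiesterase Pde4b rose 3.74-fold and the transcription factor Fosb fell 3.78-fold. Within PPAR and fatty acid oxidation 12 of 25 rose and 3 fell (13 and 3 adjusted over the list alone), with camera adjusted p = 0.031, but adjusted p = 0.135 with an estimated correlation. Lipoprotein lipase Lpl was 4.63-fold higher. Contractile smooth muscle genes fell, 9 of 13 fell and 2 rose (9 and 2 adjusted over the list alone), with camera adjusted p = 0.00387, but adjusted p = 0.19 with an estimated correlation, including transgelin Tagln (6.28-fold).

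At day 7 in DM2, H2-M10.1, of a cluster of similar class I antigen genes, had 0 counts at day 0 and reached 75.8 ± 9.12 CPM (at least 724-fold). S100a8, a calcium-binding protein of neutrophils, reached 169 ± 28.6 CPM (9820-fold (95% counting interval 1760 to 388000)). The ferritin receptor Scara5 (at least 326-fold), the trypsin Try5, with many paralogs (at least 283-fold), Ceacam10 (at least 195-fold) and the checkpoint receptor Pdcd1 (at least 166-fold) also rose from 0 counts. Falls were led by the collagen Col8a1 (205-fold), the signalling adaptor Traf1 (129-fold), Serpinb2 (121-fold), the growth factors Fgf5 (101-fold) and Wnt10b (97.6-fold), and Glipr1 (64.8-fold), with adjusted p for the 12 genes of 7.1e-11 to 4.23e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all 8854 genes changed, 3921 higher and 4933 lower (2825 and 6507 under library totals alone), 1732 and 2245 by at least 2-fold. Without DM2 replicate 2, Serpinb2 fell 193-fold (95% counting interval 53.2 to 1590).

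Unfolded protein and amino acid stress genes rose, 16 of 17 rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 6.31e-12: the chaperone Hspa5 stood at 3424 ± 463 CPM, and the stress regulators Ddit3 (18.4-fold) and Trib3 (13.9-fold) rose. Glycolysis followed, 11 of 18 rose and 0 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 0.000755, but adjusted p = 0.397 with an estimated correlation, led by the glucose transporter Slc2a1 (4.82-fold). Gapdh needs caution in this list, since its counts can be split with its many pseudogenes: its replicates stood at 2638 and 546 CPM at day 0, 1337 and 387 in DM1 at day 2, and 487 and 3020 in DM3 at day 2. In the insulin and IGF list 13 of 19 rose and 3 fell (13 and 3 adjusted over the list alone), with camera adjusted p = 3.47e-05, but adjusted p = 0.186 with an estimated correlation. The binding protein Igfbp3 rose 67.4-fold. Slow fibre genes rose, 12 of 14 rose and 1 fell (12 and 1 adjusted over the list alone), with camera adjusted p = 6.9e-08, but adjusted p = 0.0567 with an estimated correlation, among them myoglobin Mb (53.9-fold). Myh3 stood at 80.6 ± 8.5 CPM and Myog at 32.1 ± 0.131 CPM. Igfbp3 rose 106-fold without day 0 replicate 1. Mb rose 110-fold (95% counting interval 30.2 to 911) without day 0 replicate 2.

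From day 2 to day 7 in DM2, the glucose-responsive Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883) fell 419-fold, from 547 ± 42.8 to 1.3 ± 0.139 CPM. Col8a1 fell 29.9-fold, the oxysterol hydroxylase Cyp39a1 16-fold and the kinase Alpk2 15.4-fold. Nitric oxide synthase Nos2 rose 324-fold, Try5 1510-fold (95% counting interval 272 to 59900), H2-M10.1 1290-fold (95% counting interval 443 to 6280) and Pdcd1 444-fold (95% counting interval 123 to 3670); edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 3.62e-10 to 5.94e-05. The stress list rose in full, 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 2.31e-19, and of glycolysis 13 of 18 rose and 2 fell (14 and 2 adjusted over the list alone), with camera adjusted p = 3.13e-06, but adjusted p = 0.271 with an estimated correlation. Changed genes were 8754, 4063 higher and 4691 lower (2665 and 6554 under library totals alone), 1442 and 2262 by at least 2-fold. Nos2 rose 202-fold without DM2 replicate 2 of day 2 and 870-fold (95% counting interval 156 to 34400) without replicate 1.

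In DM3 at day 2, Ckm rose by 709-fold (95% counting interval 127 to 28100), the muscle splicing factor Rbm24 316-fold, Myh3 247-fold, to 142 ± 21.9 CPM, and Rgs2 188-fold. Myog rose with log2 6.91 ± 0.18. The annexin Anxa8 fell 34.3-fold, the folate enzyme Shmt1 26.4-fold, the neurofilament Nefm 25.6-fold and the epithelial protein Sprr1a 25.5-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the 8 genes had adjusted p of 1.62e-10 to 0.000123. The 8138 genes changed were 4080 higher and 4058 lower (3740 and 4751 without DM3 replicate 1), 1629 and 1545 by at least 2-fold. Rbm24 rose 685-fold (95% counting interval 123 to 27100) without day 0 replicate 1 and 223-fold (95% counting interval 76.1 to 1080) without replicate 2. Replicate 2 of DM3 stood at 62.477 on the third principal component (12.6% of the variance), against 0.925 for replicate 1. The rank correlation between these replicates, 0.957, was the lowest of the 7 groups.

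Myogenic regulators and fusion genes rose in DM3 by day 2, 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone), with camera adjusted p = 1.59e-12. The fusion peptide gene Gm7325 rose 168-fold. PPAR and fatty acid oxidation rose too, 18 of 25 rose and 3 fell (18 and 3 adjusted over the list alone), with camera adjusted p = 0.00119, but adjusted p = 0.0509 with an estimated correlation, as did fatty acid synthesis, 10 of 17 rose and 1 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00118, but adjusted p = 0.159 with an estimated correlation, including the phosphatase Lpin1 (4.59-fold). Reserve myoblast genes moved in both directions, 9 of 15 rose and 3 fell (9 and 3 adjusted over the list alone), with camera adjusted p = 0.0204, but adjusted p = 0.24 with an estimated correlation; the Notch ligand Dll1 rose 35.3-fold and Id2 fell 7.44-fold.

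By day 7 in DM3, sarcomere genes had risen over day 0. Myh3 reached 3201 ± 103 CPM (5577-fold), Acta1 12964 ± 614 CPM (3682-fold) and Ckm 199 ± 10.7 CPM (11500-fold (95% counting interval 2070 to 456000)). The muscle proteins Smpx (at least 552-fold) and Pgm5 (at least 445-fold) and the kinase Nmrk2 (at least 256-fold) rose from 0 counts, and the stretch-responsive Ankrd2 rose 6070-fold (95% counting interval 1680 to 50200). Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548) stood at 1052 ± 81.4 CPM. Dock8 fell 290-fold (95% counting interval 99 to 1410), the R-spondin receptor Lgr6 129-fold, the zinc receptor Gpr39 123-fold, Car8 103-fold, Npr3 92.7-fold and the oestrogen receptor Gper1 86.3-fold. Adjusted p of the 12 genes were 5.56e-12 to 5.96e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 9428 genes changed were 4613 higher and 4815 lower (3577 and 6101 under library totals alone), 2240 and 2396 by at least 2-fold. Without DM3 replicate 2, Car8 fell 173-fold (95% counting interval 59.1 to 840), and without replicate 1 Gper1 fell 136-fold (95% counting interval 37.6 to 1130).

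Core sarcomere genes rose in DM3 at day 7, 21 of 22 rose and 1 fell (21 and 1 adjusted over the list alone), with camera adjusted p = 7.89e-18, as did excitation-contraction genes, 18 of 22 rose and 1 fell (18 and 1 adjusted over the list alone), with camera adjusted p = 4.57e-14, including the calcium channel Cacna1s (438-fold). For fast fibre genes 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 1.68e-13, and for slow fibre genes 13 of 14 rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 6.01e-12; the fast light chain Mylpf rose 1670.1-fold and Mb 1035-fold. Oxidative phosphorylation rose, 21 of 30 rose and 0 fell (21 and 0 adjusted over the list alone), with camera adjusted p = 0.00285, but adjusted p = 0.623 with an estimated correlation. Mitochondrially encoded genes rose with it, 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00753, but adjusted p = 0.454 with an estimated correlation, in the libraries whose mitochondrial mRNA share stood highest (5.44 and 5.01%). The imprinted growth factor Igf2 rose 167-fold and the noncoding H19 reached 27408 ± 1913 CPM. Mb rose 2110-fold (95% counting interval 585 to 17500) without day 0 replicate 2.

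**Figure D2:**
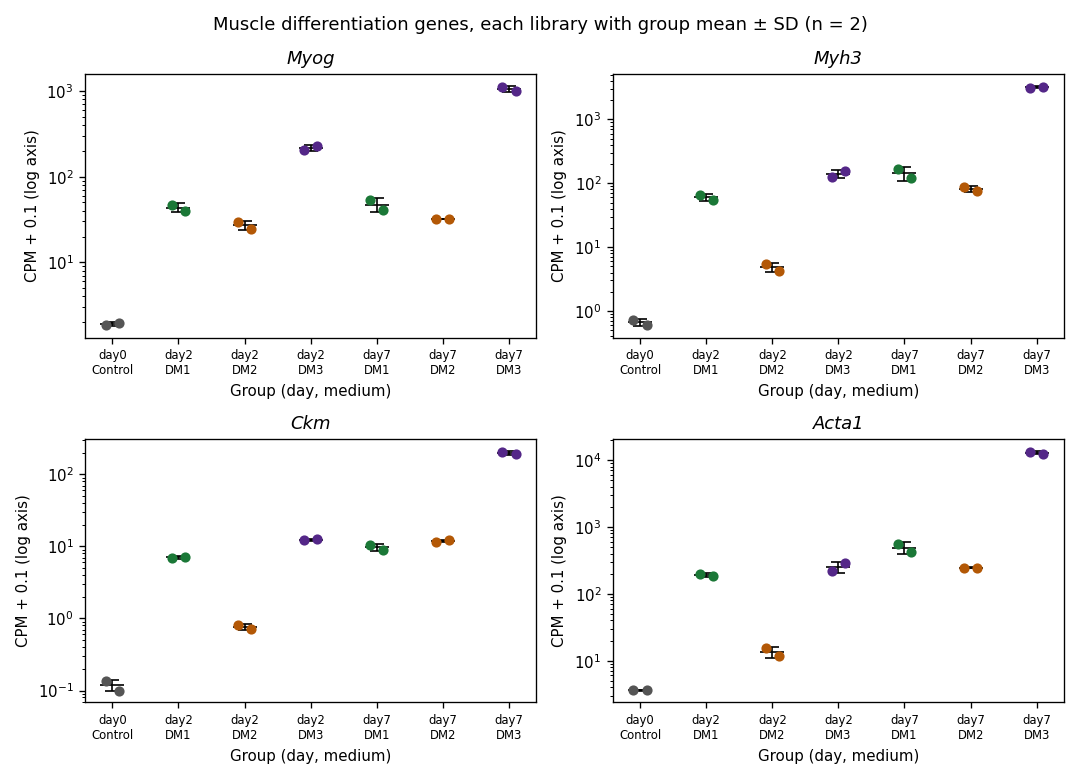
Levels of muscle genes in each library of the 7 groups.

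Between day 2 and day 7 in DM3, slow myosin-binding protein C Mybpc1 rose 2080-fold (95% counting interval 575 to 17200), the Z-disc protein Actn2 199-fold, Ankrd2 141-fold and fast Mybpc2 120-fold. The integrin Itgb7 fell 32.9-fold, the adhesion molecule L1cam 15.9-fold, the hedgehog inhibitor Hhip 15.1-fold and the transcription factor Sox8 11.7-fold; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave the 8 genes 4.52e-09 to 0.000193. Developmental sarcomere isoforms rose in full, 8 of 8 rose and 0 fell (8 and 0 adjusted over the list alone), with camera adjusted p = 1.38e-10, but adjusted p = 0.062 with an estimated correlation, and fatty acid synthesis fell, 12 of 17 fell and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00398, but adjusted p = 0.19 with an estimated correlation, led by the elongase Elovl6 (6.51-fold). Changed genes were 7653, 3617 higher and 4036 lower (2486 and 5587 under library totals alone, 4434 and 3773 without DM3 replicate 1 of day 2), 1254 and 1469 by at least 2-fold. Actn2 rose 93.5-fold without DM3 replicate 2 of day 2 and at least 196-fold without replicate 1. Itgb7 fell 21.3-fold and 73.1-fold without DM3 replicate 1 and 2 of day 7.

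At day 2, adding the cocktail to 2% HS (DM3 against DM1) raised Prg4 231-fold, Ctla2a 97.1-fold, Serpina3n 92.7-fold and Rgs2 75.3-fold. Myog was 5-fold higher, at 218 ± 18.9 against 43.5 ± 5.18 CPM, and Acta1 did not pass (log2 0.41 ± 0.16). The matrix proteins Adamtsl3 (39.6-fold) and Olfml3 (22.1-fold), Dock8 (36-fold) and the BMP antagonist Grem1 (17.9-fold) were lower. Adjusted p of the 8 largest changes were 2.99e-10 to 2.11e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 5908 genes changed, 2813 were higher and 3095 lower (2316 and 3602 under library totals alone), 678 and 1118 by at least 2-fold. The split was 1838 higher and 2318 lower without DM1 replicate 2, 2598 and 3796 without DM3 replicate 1, and 1508 and 1859, 3367 in all, without the 3 libraries of low pseudogene share. Serpina3n was 182-fold (95% counting interval 50.3 to 1510) higher without DM1 replicate 2. Without DM3 replicate 1, Acta1 passed (log2 0.5898, adjusted p = 0.0159).

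Glucocorticoid targets were higher with the cocktail, 15 of 19 rose and 1 fell (15 and 1 adjusted over the list alone), with camera adjusted p = 2.18e-13; Fkbp5 was 6.88-fold higher. For myogenic regulators and fusion 11 of 19 rose and 1 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 1.89e-08, and of PPAR and fatty acid oxidation 14 of 25 rose and 3 fell (15 and 3 adjusted over the list alone), with camera adjusted p = 0.000488. The fatty acid transporter Cd36 was 4.34-fold and the fatty acid carrier Fabp4 12.9-fold higher. Matrix genes were lower, 14 of 25 fell and 4 rose (14 and 4 adjusted over the list alone), with camera adjusted p = 0.000224, but adjusted p = 0.3 with an estimated correlation, and so was the cell cycle list, 23 of 30 fell and 1 rose (23 and 1 adjusted over the list alone), with camera adjusted p = 1.71e-14, where cyclin Ccnd1 was 8.56-fold lower.

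With 2% HS in place of 10% FCS at the same cocktail (DM3 against DM2, day 2), muscle genes were higher: Myh3 30.1-fold, Casq2 21.4-fold, Acta1 18.9-fold, Ckm 18.2-fold and Myog 8.08-fold. Lower were Id2 (12.9-fold) and Id3 (6.71-fold), Sprr1a (9.21-fold) and the placental hormone gene Prl2c2 (6.91-fold), which has near-identical copies. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay at 4.48e-08 to 0.00465. The count of 2602 genes (1594 higher, 1008 lower; 348 and 219 by at least 2-fold) depended on the libraries, and so did its direction. It was 494 (353 higher, 141 lower) with only these groups fitted, 1124 (733 and 391) without DM2 replicate 1, 4130 (1860 and 2270) without DM3 replicate 1 and 1188 (772 and 416) without DM3 replicate 2. Without the 3 libraries of low pseudogene share it was 948 (636 and 312), and 1074 (671 and 403) with that share as a covariate. Library totals alone gave 1345 higher and 1302 lower, DESeq2's size factors 1432 and 1131, and protein-coding genes only 1586 and 1504. Without DM3 replicate 2, Sprr1a no longer passed (7.21-fold, adjusted p = 0.0674).

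Core sarcomere members were higher in DM3, 18 of 22 rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 7.67e-32, as were myogenic regulators, 14 of 19 rose and 2 fell (14 and 3 adjusted over the list alone), with camera adjusted p = 1.28e-19. Glucocorticoid targets did not pass as a list, 3 of 19 fell and 3 rose (4 and 3 adjusted over the list alone), with camera adjusted p = 0.553. In glycolysis 0 of 18 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.352.

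DM2 against DM1 at day 2, where serum and cocktail both differ, had Orm1 (at least 154-fold), Ceacam10 (at least 82.8-fold), Prg4 (331-fold) and Ctla2a (106-fold) higher. The channel gene Tmc3 (88.3-fold), the signal Wnt7b (41.6-fold), Dock8 (40.7-fold) and the synaptic Nptx1 (33.6-fold) were lower, with adjusted p of 2.56e-10 to 2e-06 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Slow fibre genes were lower, 11 of 14 fell and 0 rose (11 and 0 adjusted over the list alone), with camera adjusted p = 1.44e-07, but adjusted p = 0.0567 with an estimated correlation, and fast fibre genes as well, 11 of 17 fell and 0 rose (12 and 0 adjusted over the list alone), with camera adjusted p = 1.45e-06, but adjusted p = 0.121 with an estimated correlation. Changed genes were 6290, 2797 higher and 3493 lower, 825 and 1205 by at least 2-fold. The split was 1801 and 2530 without DM1 replicate 1, and 1791 and 2653 without DM1 replicate 2. Without DM2 replicate 1, Tmc3 was 155-fold (95% counting interval 52.9 to 753) lower.

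At day 7, the cocktail at 2% HS (DM3 against DM1) went with much higher muscle genes. Myh3 was 22.2-fold higher, Acta1 26.4-fold, Ckm 20.6-fold and Myog 22.3-fold, at 1052 ± 81.4 against 47.2 ± 8.95 CPM. The fusion gene Tmem8c (ENSMUSG00000009214, chromosome 2, 27061636 to 27072179) was 9.16-fold higher. Nmrk2 (226-fold), Mybpc1 (52.3-fold), the claudin Cldn2 (66.7-fold), the growth factor Gdf5 (50.4-fold), Ceacam10 (39.4-fold) and the muscle fatty acid carrier Fabp3 (39.3-fold) led the rises. Cilp (186-fold), Sprr1a (57.5-fold), the matrix protein Spon2 (43.3-fold), the interferon-related 9930111J21Rik2 (39-fold), Col8a1 (35.4-fold) and the Wnt inhibitor Dkk2 (34.9-fold) led the falls. These 12 genes had adjusted p of 9.92e-10 to 0.00127 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 7622 genes changed, 3620 were higher and 4002 lower (2172 and 5786 under library totals alone), 884 and 1871 by at least 2-fold. Without DM1 replicate 1, Nmrk2 was at least 214-fold higher, Ceacam10 103-fold (95% counting interval 35 to 500) and Fabp3 19-fold. Without DM1 replicate 2, Nmrk2 was 123-fold higher, Ceacam10 25.6-fold and Fabp3 at least 119-fold, and Sprr1a was 31.1-fold lower.

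In this comparison the core sarcomere rose, 20 of 22 rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 2.81e-18, and fast and slow fibre genes rose together: 13 of 17 rose and 0 fell (14 and 0 adjusted over the list alone) with camera adjusted p = 7.62e-14, and 11 of 14 rose and 1 fell (12 and 1 adjusted over the list alone) with camera adjusted p = 4.57e-14. Fast Mybpc2 was 22.6-fold and fast troponin Tnni2 23.5-fold higher, and slow troponin Tnnc1 18.5-fold. Oxidative phosphorylation was higher, 29 of 30 rose and 0 fell (29 and 0 adjusted over the list alone), with camera adjusted p = 1.72e-09, but adjusted p = 0.321 with an estimated correlation, led by cytochrome gene Cyc1 (2.61-fold). Matrix genes were lower, 20 of 25 fell and 1 rose (20 and 1 adjusted over the list alone), with camera adjusted p = 5.03e-11, but adjusted p = 0.0995 with an estimated correlation; Col1a1 was 12.8-fold and periostin Postn 15.6-fold lower. So were interferon genes, 16 of 22 fell and 1 rose (17 and 1 adjusted over the list alone), with camera adjusted p = 0.000142, but adjusted p = 0.0825 with an estimated correlation, among them the antiviral Ifit3 (8.07-fold). Glucocorticoid targets did not pass as a list, 7 of 19 rose and 6 fell (7 and 6 adjusted over the list alone), with camera adjusted p = 0.362, while Pde4b was 5.58-fold higher.

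**Figure D3:**
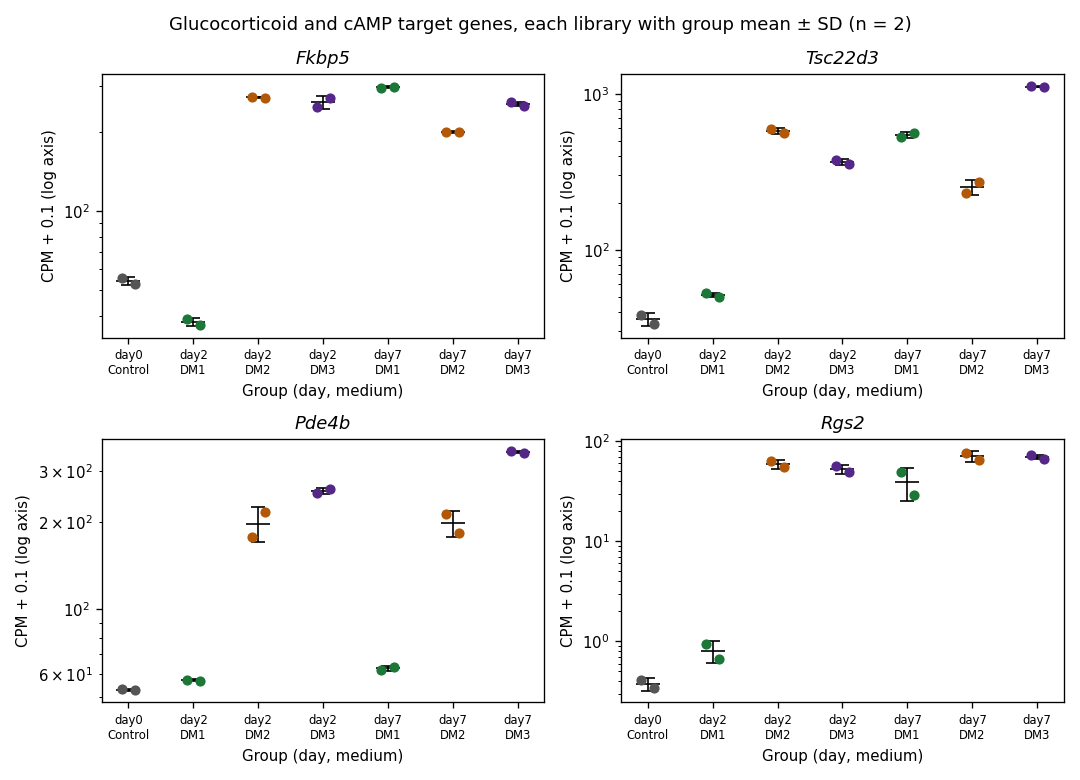
Levels of genes that respond to the components of the cocktail in each library of the 7 groups.

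With 2% HS in place of 10% FCS at the same cocktail (DM3 against DM2, day 7), Txnip was 356-fold higher, at 465 ± 0.743 CPM, the muscle protein Klhl41 99.7-fold, Ankrd2 73-fold, Mybpc2 104-fold and the protease Adamts16 124-fold. Atcayos (chromosome 10, 81194609 to 81210877, plus strand) was 179-fold higher, at 52.1 against 0.287 CPM. Nmrk2 (81198170 to 81202051, minus strand) lies wholly within it and stood at 26.8 against 1.09 CPM, while Atcay, which overlaps Atcayos on the minus strand, stood at 0.0205 and 0 CPM. Whether the reads of this interval were assigned to the right strand was not tested here. Lower were H2-M10.1 (1820-fold (95% counting interval 504 to 15100)), the receptor Gpr141 (605-fold (95% counting interval 108 to 23900)), the actin-binding Avil (467-fold), Pdcd1 (278-fold (95% counting interval 94.7 to 1350)), the transcription factor Taf7l (268-fold (95% counting interval 73.8 to 2220)) and coagulation factor F5 (169-fold). Myog was 32.8-fold and Myh3 39.7-fold higher; the 12 largest changes had adjusted p of 5.74e-11 to 5.6e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In total 8420 genes changed, 4393 higher and 4027 lower, 1979 and 1660 by at least 2-fold. Without DM2 replicate 2, Mybpc2 was 165-fold (95% counting interval 45.4 to 1360) higher.

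Stress genes were lower in DM3 than in DM2, 17 of 17 fell and 0 rose (17 and 0 adjusted over the list alone), with camera adjusted p = 2.18e-14; Hspa5 stood at 872 ± 15.6 CPM. Glycolysis was lower, 13 of 18 fell and 2 rose (15 and 2 adjusted over the list alone), with camera adjusted p = 5.75e-05, but adjusted p = 0.325 with an estimated correlation, including Slc2a1 (6.09-fold). Cell cycle genes were lower, 28 of 30 fell and 0 rose (28 and 0 adjusted over the list alone), with camera adjusted p = 6.31e-15, and cholesterol synthesis higher, 19 of 22 rose and 2 fell (19 and 2 adjusted over the list alone), with camera adjusted p = 0.000153, but adjusted p = 0.254 with an estimated correlation. Myogenic regulators were higher, 17 of 19 rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 1.32e-14.

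DM2 against DM1 at day 7 had H2-M10.1 (at least 606-fold), Pdcd1 (at least 138-fold), S100a8 (953-fold), the epoxide hydrolase Ephx2 (327-fold), the collagenase Mmp13 (316-fold) and Scara5 (281-fold) higher. Postn (574-fold), Txnip (574-fold), the sodium channel Scn7a (306-fold), Cilp (727-fold (95% counting interval 201 to 6010)), Col8a1 (115-fold) and Wnt7b (113-fold) were lower. Adjusted p of these 12 genes lay at 1.81e-10 to 8.82e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Matrix genes were lower as a list, 23 of 25 fell and 1 rose (23 and 1 adjusted over the list alone), with camera adjusted p = 3.51e-12, but adjusted p = 0.0896 with an estimated correlation. The stress list was higher, 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 4.49e-11, and so were cell cycle genes, 22 of 30 rose and 5 fell (22 and 5 adjusted over the list alone), with camera adjusted p = 7.45e-07, but adjusted p = 0.121 with an estimated correlation, including Cdc6 (12.2-fold). Changed genes were 9238, 4227 higher and 5011 lower (2763 and 6679 under library totals alone), 1357 and 2719 by at least 2-fold. Without DM1 replicate 1, S100a8 was 2030-fold (95% counting interval 561 to 16700) higher, Ephx2 215-fold, Mmp13 188-fold and Scara5 160-fold. Without DM1 replicate 2, Ephx2 was 642-fold (95% counting interval 178 to 5310) higher, Mmp13 906-fold (95% counting interval 162 to 35800) and Scara5 958-fold (95% counting interval 172 to 37900). Scn7a was 203-fold lower without DM2 replicate 1. Without DM2 replicate 2, Scn7a was 644-fold (95% counting interval 178 to 5320) lower and Wnt7b 207-fold (95% counting interval 57.1 to 1710).

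**Figure D4:**
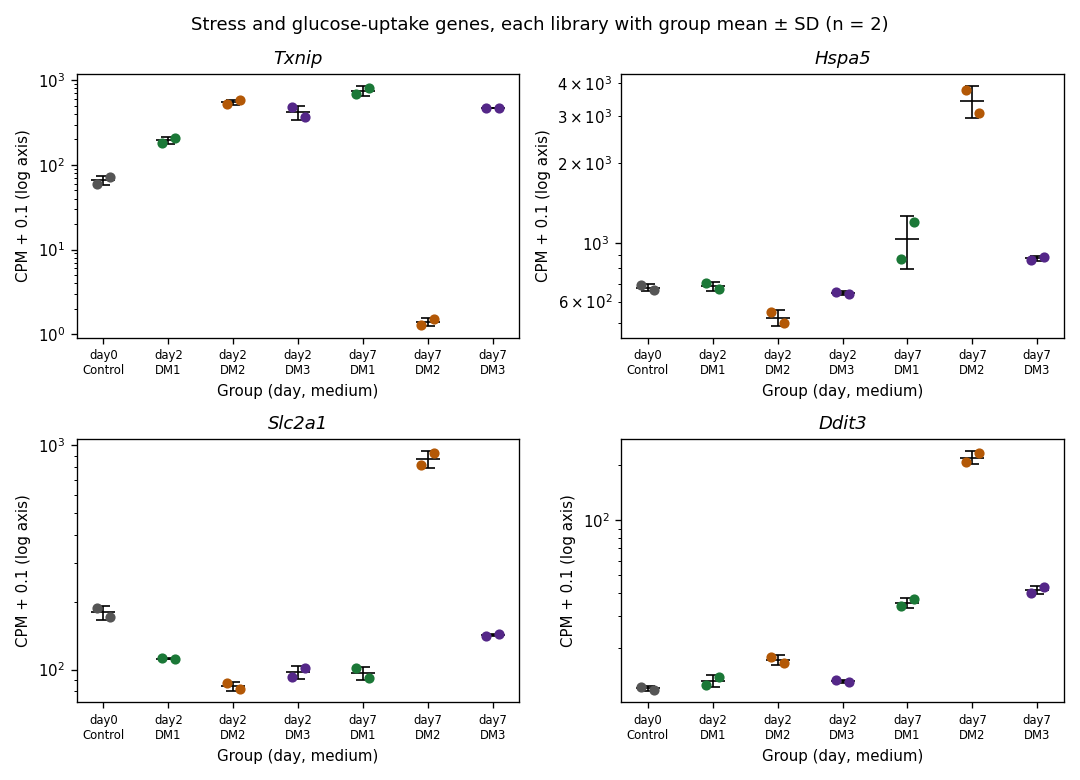
Levels of stress and glucose-responsive genes in each library of the 7 groups.

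The difference between DM3 and DM1 itself differed between the days for 5582 genes, 2596 more positive and 2986 more negative at day 7 (1797 and 4097 under library totals alone, 2762 and 2546 by DESeq2's Wald test, 3440 and 2877 without DM3 replicate 1 of day 2). For Myog it grew by log2 2.16 ± 0.19, for Acta1 by 4.31 ± 0.24 and for Ckm by 3.55 ± 0.17; for Fkbp5 it changed by -3.00 ± 0.10 and for Fabp4 by -5.19 ± 0.56. The difference between DM3 and DM2 changed with the day for 6362 genes, 3197 more positive and 3165 more negative (3572 and 2865 under library totals alone, 4178 and 3158 without DM3 replicate 1 of day 2), with Txnip at 8.85 ± 0.24, Myog at 2.02 ± 0.19 and the coactivator Ppargc1a at -3.57 ± 0.24.

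Among myosin heavy chain isoforms, whose reads can be split between the near-identical genes of the cluster, Myh3 took 98.5 ± 0.0407% of counts in DM3 at day 7, 92.5 ± 0.0446% in DM2 and 81.5 ± 1.24% in DM1 (n = 2 each). Slow Myh7 took 9.29 ± 0.907% in DM1, 3.51 ± 0.271% in DM2 and 0.928 ± 0.0907% in DM3, and fast Myh1 4.16 ± 0.019%, 1.59 ± 0.0899% and 0.1 ± 0.0095%. Myh7 in CPM was 16.6 ± 5.78 in DM1 and 30.1 ± 2 in DM3, a difference that did not pass (log2 0.85 ± 0.38). Myh1 leaned the other way, with fewer expected counts in each DM3 library of day 7 than in either DM1 library. Differences in share were not tested here. After division by exon length Myh3 took 85.4% and Myh7 6.85% in DM1 at day 7.

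Of the lists of other cell types, adipocyte markers passed in 4 of 15 comparisons, 1 of them within the medium without the cocktail, and in 0 with an estimated correlation. In DM1 from day 2 to day 7, 5 of 11 rose and 0 fell (5 and 0 adjusted over the list alone), with camera adjusted p = 0.042, but adjusted p = 0.352 with an estimated correlation; camera gave 0.076 without DM1 replicate 2 of day 2, 0.0591 without DM1 replicate 2 of day 7 and 0.0697 with the replicate block. In DM3 at day 2 the list passed against day 0, 6 of 11 rose and 2 fell (6 and 2 adjusted over the list alone), with camera adjusted p = 0.0368, but adjusted p = 0.333 with an estimated correlation. Without day 0 replicate 2 that was 0.0576, and without DM3 replicate 2 it was 0.0563. It also passed there against DM1, 5 of 11 rose and 1 fell (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0116, but adjusted p = 0.273 with an estimated correlation. In DM2 at day 7 against day 0, 5 of 11 rose and 1 fell (5 and 1 adjusted over the list alone), with camera adjusted p = 0.0466, but adjusted p = 0.35 with an estimated correlation, and fgsea adjusted p = 0.205; camera gave 0.0563 without day 0 replicate 2 and 0.0579 without DM2 replicate 2. In DM2 at day 2 the list passed only when 1 library was left out, against day 0 (0.0259 without day 0 replicate 1, 0.0436 without DM2 replicate 2) and against DM1 (0.0427 without DM1 replicate 1, 0.0479 without DM2 replicate 2). In DM2 at day 7 Fabp4 stood at 6.74 ± 0.897 CPM and the lipid-droplet protein Plin1 at 0.917 ± 0.0867 CPM, while Adipoq and Ucp1 did not pass the low-count filter. Brown or beige, endothelial, and osteoblast and chondrocyte markers passed as lists in 0 of the 15 comparisons with all libraries, and in some with 1 library left out (lowest adjusted p = 0.0338, 0.0482 and 0.035). In DM2 at day 7 against day 0, of brown or beige markers 5 of 7 rose and 1 fell (5 and 1 adjusted over the list alone), with camera adjusted p = 0.0672 (0.0499 without DM2 replicate 1). Ppargc1a rose 16.7-fold. Of endothelial markers 3 of 6 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0742, and of osteoblast and chondrocyte markers 5 of 7 fell and 2 rose (5 and 2 adjusted over the list alone), with camera adjusted p = 0.563. Inflammatory genes moved in both directions there, 9 of 17 rose and 6 fell (9 and 7 adjusted over the list alone), with camera adjusted p = 0.392; they passed in 1 comparison, DM1 at day 2 against day 0, where 7 of 17 rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00236, but adjusted p = 0.0842 with an estimated correlation. Of 13 leukocyte markers, 1 passed the low-count filter, Cd14, at 6.8 ± 0.349 CPM in DM2 at day 7.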

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

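The tests of read division between genes and pseudogenes, of genomic DNA, of DM2 or DM3 cultures under a wrong label, of Hsd11b1 and of leukocytes were chosen only after the result was seen.

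The difference between DM3 and DM1 was tested for a change between day 2 and day 7, and 5582 genes passed. Per gene, the log2 change of that difference was 5.456 for Nptx1, 5.403 for Gdf5 and 6.236 for Mybpc1, which had 2 and 3 counts in DM3 and DM1 at day 2 (95% counting interval 3.14 to 9.87). Serpina3m, Orm1 and the zinc finger gene Zxda had 0 counts in DM1 at day 2, so their fitted values of -11.24, -9.714 and -7.844 depend on the fit's handling of 0, and the counts support only -6.53, -5 and -3.13 or lower. For muscle genes it was 1.066 for Myod1, 2.156 for Myog, 3.103 for Tmem8c, 3.241 for Myh3, 2.952 for Myh7, 3.549 for Ckm and 4.309 for Acta1. For fat and cocktail genes it was -0.5142 for Pparg, -1.464 for Cebpa, -5.194 for Fabp4, -2.84 for Pdk4, -2.996 for Fkbp5 and -1.801 for Tsc22d3, and for growth and matrix genes -0.7851 for Mki67, 0.5169 for Ccnd1, -1.494 for Col1a1 and 2.277 for Igf2. Leaving out 1 library ended the call of Mybpc1 without DM1 replicate 2 of day 2 (adjusted p 0.933), of Mki67 for 6 of the 8 libraries (up to 0.12) and of Pparg for 7 (up to 0.146). Gdf5 stood at 4.76 without DM1 replicate 1 of day 2 and 6.081 without DM3 replicate 2 of day 2, and Myh7 at 3.658 without the latter.

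The difference between DM3 and DM2 changed between the days for 6362 genes. The log2 change was 8.852 for Txnip, 5.365 for the cytokine receptor Il2rb and -7.533 for F5. With 1 to 3 counts in at least 1 group, it was 5.456 for Mybpc2 (95% counting interval 1.73 to 8.34), -8.045 for Gpr141 (-13.9 to -3.56) and -8.012 for Pdcd1 (-12.3 to -3.8). It was 2.628 for Myod1, 2.021 for Myog, 0.7498 for Tmem8c and 1.488 for Acta1. For fat and cocktail genes it was 0.6749 for Pparg, 1.985 for Cebpa, -1.405 for Fabp4, -0.5189 for Lpl, 1.268 for Cd36, 2.38 for Pdk4, -0.872 for Angptl4, 0.4175 for Fkbp5, 2.806 for Tsc22d3, -3.574 for Ppargc1a and 0.4365 for Pde4b. Mki67 gave -1.235, Ccnd1 -1.22, Col1a1 2.207 and Igf2 2.354. Leaving out 1 library of day 2 ended the call of Mybpc2 (DM2 replicate 2, adjusted p 0.906), Gpr141 (DM3 replicate 1, 0.965) and Pdcd1 (DM3 replicate 2, 0.977, and DM2 replicate 1 and 2, 0.0593 and 0.0552). Calls also ended for Fabp4 with 4 of the 8 libraries (up to 0.122), Lpl with 3 (up to 0.0957) and Pde4b with 5 (up to 0.103).

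Replicate 1 of day 0, replicate 1 of DM1 at day 2 and replicate 2 of DM3 at day 2 each had a lower share of counts on processed pseudogenes than the other library of the group, and no biological explanation was tested. Over 88, 82 and 72 gene families, the median log2 ratio to the other library was -1.19, -0.871 and -4.32 for pseudogenes, 0.23, 0.12 and 0.186 for their parent genes, and 0.132, -0.00469 and -0.022 for the sums of both; the sums moved by at most 0.111 of the pseudogenes' ratio, consistent with reads divided differently between genes and pseudogenes. With pseudogenes left out, the deviations of replicate 1 in the 3 groups still correlated (0.7207, -0.7315 and -0.6451, against 0.7946, -0.812 and -0.7079 with them). Another check took 7228 genes with whole counts of at least 50 in each of the 14 libraries, where no sign of divided reads was seen. A shared read given wholly to 1 gene would also leave a whole count. There the 3 correlations taken by low library were 0.264 to 0.4246, within the 0.4935 reached by other pairs of groups. A further difference stays open. The checks also differ in the counts of their genes and in the measure, log2 ratios in place of deviations from the group mean. Their correlations therefore cannot be set against each other. Genomic DNA in the other libraries as the whole difference is argued against, since it would add to pseudogenes whatever the RNA level of their parents: the excess was 11.6, 11.2 and 27.2 CPM per kb over 350, 319 and 342 processed pseudogenes of parents at 100 CPM or more, but -0.00552, 0.00353 and -0.00529 over 24, 23 and 23 of parents under 1 CPM, and the 95% intervals of the ratio, over pseudogenes, ended at 0.00292 or lower. A smaller part from genomic DNA cannot be told apart, since of the log2 ratios of olfactory and vomeronasal receptor genes, -0.428, 0.0234 and -0.533, only the last exceeded in size the 0.452 reached between replicates of the other 4 groups; a first bound for these ratios, which that of day 0 reached, took account of counting error alone and was dropped.

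Glucocorticoid targets were raised in DM1 at day 7, a medium without dexamethasone per the labels. Other genes that were higher with the cocktail at day 2 differed among themselves. Pde4b stood at 62.5 CPM in DM1 at day 7 against 198 and 349 in DM2 and DM3, and Ceacam10 at 0.312 against 12.9 CPM in DM3. Ctla2a went the other way, at 1402.5 CPM in DM1 at day 7 against 8.1 in DM1 and 787 in DM3 at day 2. Single genes such as these do not stand for the whole response to the cocktail. RNA carried over from DM3 or DM2 cultures is argued against. The glucocorticoid targets need 89.9 or 145% of such RNA, where donor-specific transcripts allow 8.88 or 14.1%, at least 10.1 times less. Cultures of DM2 or DM3 at day 7 under a wrong label are argued against, since each DM1 library differed by at least 2-fold from each of theirs in 1842 genes or more, against at most 905 between replicates. Cilp in DM1 lay 186-fold above DM3 and 727-fold above DM2 (95% counting interval 201 to 6010). It was named for its large difference in these comparisons and adds no separate support. A wrong label on another culture with the cocktail cannot be told apart, because 37 of 183 genes raised by the cocktail, 20.2%, lay at least 2-fold lower in DM1 than in DM2 and DM3 at day 7, between the bounds written for and against it. Of the same 183 genes, 155 (84.7%) were at least 2-fold higher in DM1 at day 7 than at day 0, against 2156 of all 15973 genes tested. The 183 genes were chosen partly for lying at least 2-fold above these same day 0 libraries in DM2 and DM3 at both days. Their share therefore cannot decide the question of the label. Hsd11b1 rose by log2 6.292 from day 2 to day 7 in DM1, so glucocorticoid of the serum made active by it may contribute, which cannot be told apart from a response of Hsd11b1 itself, since it was also higher with the cocktail at day 2 (log2 3.054 in DM3 and 2.227 in DM2 against DM1), and steroid levels were not measured here.

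Txnip fell while stress genes rose in DM2 at day 7, and a rise of the glycolysis list was lost with an estimated correlation (adjusted p = 0.397 against day 0 and 0.271 against day 2). Leukocytes are argued against, since 12 leukocyte markers other than Cd14 summed to 0.365 CPM, 0.216% of the rise of S100a8 by 169 CPM. Cd14, the 1 marker past the low-count filter, was left out of the sum. The other 12 had failed that filter, so a low sum was likely beforehand. Low oxygen may contribute. Of 12 low-oxygen genes 9 were higher than in DM1 (median log2 0.902) and 1, Adm, was lower (-0.694). Car9 (0.64) and P4ha1 (0.163) did not pass there. Against DM3, 12 were higher (median 0.8849). The largest rises were those of Ndrg1 (3.44 against DM1 and 4.82 against DM3) and Ero1l (3.24 and 4.08). Whether these rises belong to the stress response of the same group was not tested, so low oxygen cannot be told apart from it. Glucose run down in the medium cannot be told apart, as its marker Arrdc4 had 53 counts over the 14 libraries, too few to test. The serum named by the design, which differs in kind and amount, stays open as a biological difference and was not tested apart from these.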

How the results depend on the processing

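The tests without the 3 libraries of low pseudogene share, with that share as a covariate and with protein-coding genes only were chosen only after the result was seen; the other settings were chosen before, and each of them was run. Counts of changed genes stayed within 1.5 times under DESeq2's size factors, library totals, both filters, DESeq2's Wald test, unrounded counts, protein-coding genes and the replicate block, in all 17 comparisons. The numbers higher did not under library totals alone, which gave 2665 for DM2 at day 7 against day 2 and 2172 and 2763 for DM3 and DM2 against DM1 at day 7. Whether more genes were higher or lower reversed under at least 1 setting in 13 of the 17 comparisons. With only the compared groups fitted, DM3 against DM2 at day 2 fell to 494 genes. Without the 3 libraries it gave 948, DM1 at day 2 against day 0 gave 2134 and DM3 against DM1 at day 2 gave 3367; with the covariate DM3 against DM2 at day 2 gave 1074. Leaving out 1 library, with the lone library left in a group assumed to vary like the other groups, gave 2868 to 3582 for DM1 at day 2 against day 0, 3631 to 4191 for DM1 at day 7 against day 2 and 1124 to 4130 for DM3 against DM2 at day 2. It also moved the numbers higher to 1690 for DM1 at day 7 against day 2 and 1838 for DM3 against DM1 at day 2 without DM1 replicate 2 of day 2, and to 1801 and 1791 for DM2 against DM1 at day 2 without DM1 replicate 1 and 2. Of 405 list tests 208 passed, 57 with an estimated correlation, 198 with fgsea, 202 with the replicate block and 205 to 212 without 1 library. Single calls of named genes were lost 116 times on leaving out 1 library, 23 times without the 3 libraries, 21 with the covariate, 15 with only the compared groups, 9 each with DESeq2's Wald test and no filter, 6 with library totals, 2 with the block and 1 with DESeq2's size factors. The replicate numbers showed no steady pairing (correlations -0.812 to 0.7946 over 21 pairs of groups, median 0.0325). Library totals alone moved the median log2 fold change of all genes to -0.256 and -0.176 for DM2 and DM3 at day 7 against day 0, -0.269 and -0.171 against day 2, and -0.265 and -0.234 against DM1, and turned Pde4b in DM2 at day 7 against day 2 to -0.2556 (adjusted p 0.0474). Division by exon length moved myosin shares past 1 SD: Myh7 to 2.386% in DM1 at day 2, Myh3 to 99.69% in DM3 at day 2; in DM1 at day 7 Myh2 to 0.202%, Myh3 to 85.44%, Myh7 to 6.852% and Myh8 to 1.832%; in DM2 at day 7 Myh3 to 93.93%, Myh7 to 2.503% and Myh8 to 0.4056%; in DM3 at day 7 Myh3 to 98.89%, Myh7 to 0.6546% and Myh8 to 0.1016%. This last follows from the genes' lengths; the cause of the other shifts was not tested.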

Other observations

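The tests of this part were not chosen after the result was seen, but the genes named were picked from the lists after their values were seen. Of the inflammatory list, 6 of 17 rose and 9 fell (6 and 9 adjusted over the list alone) in DM3 against DM1 at day 7, with camera adjusted p = 0.48, and 3 members are given here. The cytokine Il6 stood at 21.1 ± 1.55 CPM in DM3 at day 7 against 4.59 ± 0.82 in DM1 and 3.91 ± 0.909 in DM2 (n = 2 each), and the acute-phase gene Saa3 at 5.02 ± 0.427 CPM against 0.526 ± 0.567 and 0.746 ± 0.00955. The protease Mmp3 went the other way, 17.8-fold lower than in DM1 and 35-fold lower than in DM2.

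Id1 and Id2, which hold back differentiation, were highest in DM2 at day 2. Id2 stood at 96.5 ± 7.35 CPM in DM2, 7.48 ± 1.62 in DM3 and 17.7 ± 4.36 in DM1, and Id1 at 53.6 ± 10.7, 12 ± 3.45 and 8.41 ± 0.867 CPM. By day 7 Id2 in DM2 was at 14.8 ± 0.139 CPM.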
